A study of Mus musculus with 8 samples.

How the data were processed

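The data are 8 arrays of dermal fibroblasts sorted from female mice on a normal diet (ND, 4 arrays) or a high fat diet (HFD, 4 arrays), with groups and specimen numbers taken from the labels. The deposited table holds log2 expression values of 45141 probe sets, from 3.56 to 13.5 with 2 decimals. Per the submitters' processing notes the authors used RMA and the affy package, with versions and settings not given in the sources used here. The quartiles of the 8 arrays agree within 0.04 log2, so a change in the total RNA of the cells would not be visible in these values, and the deposited values were used without further scaling. No detection calls or scanner values were used, so signal near the background is known only from the level itself. Amplification over 20 cycles from 10000 sorted cells can weaken the relation between RNA amount and signal. No pair of arrays was a duplicate, since the SD of their difference over probe sets was 0.165 or more.

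Probe sets were named from the platform annotation, which lists 29449 of them, 28898 with 1 gene symbol and 551 with several, while 15588 others were unnamed here apart from 104 control probe sets. Symbols were updated by Entrez identifier for 28689 probe sets through a table of the GRCm38.p6 assembly, used for names only. No coordinates are printed because the build of the array design is not given in the sources used here. Each gene was represented by its named probe set with the highest mean over the 7 arrays of the comparison, which left 17097 genes, 7180 of them with more than 1 probe set.

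Before the data were examined, the comparison was set as HFD 1 to 4 against ND 1 to 3, without ND 4, which the labels exclude by quality control. It was fitted in limma 3.58.1 under R 4.3.3 with lmFit and eBayes (trend on mean expression, 10.3 total degrees of freedom), and p-values were adjusted by Benjamini-Hochberg over all genes at 0.05. Adjusted p-values in the text come from this limma fit. Up to 12 genes per direction with the largest change were named, among those past the threshold whose HFD and ND arrays do not overlap, leaving out RIKEN, predicted, LOC and tag symbols. The rule would have filled a shorter direction with the smallest unadjusted p among brighter genes changed at least 1.5-fold, given as values, which was not needed. It also names up to 4 members of each list by smallest p and 7 genes of the sort. Further members past the threshold and others named were chosen after their values were seen, as were the tests that the closing section marks.

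Also fixed beforehand were 35 gene lists, for matrix, lipid, energy, immune, stress and signalling genes, dermal layers, the sort and 10 other cell types. The ribosomal protein list was first coded wrongly, and was corrected to its fixed definition after its first result had been seen. Some members were not analysed here because no probe set names them alone. Lists were tested with camera (preset correlation 0.01) and adjusted over the 35 lists, with a correlation estimated per list and fry as alternatives. Camera compares a list with other genes, and fry asks only whether its members change. The distance between diets and the spread within them were tested exactly over the 35 splits of 7 arrays into 3 and 4. Figures were drawn with matplotlib 3.10.9.

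Other settings chosen beforehand were all 8 arrays, leaving out each array, the specimen number as a block, leaving out the dimmer genes, quantile normalization, median centring, eBayes without trend or robust, array weights, the mean of probe sets, every probe set alone, a residual component, and other thresholds. Added after seeing the data were the split of the arrays by the background of GC-rich nonspecific probe sets as a block, the arrays on its low side alone, the mean of the keratinocyte list as a covariate, and the mean 3′ minus 5′ difference of the Gapdh and Actb control probe sets as a covariate.

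The fit was tested on simulated data with the real means and spreads of 17097 genes, 200 of them changed, over 20 simulations. For 3 ND against 4 HFD arrays it recovered 95% of the genes changed by 1 log2 and 65% of those changed by 0.5, with 5% false calls. For 2 against 4 arrays it recovered 90% and 51.1%, and for 3 against 3 arrays 92.4% and 52%. In all of these the genes were drawn without correlation, so the rates need not hold for the correlated genes of the real arrays. A shift of 0.2 log2 in the 47 oxidative phosphorylation genes, simulated without correlation between genes, was called by camera in 20 of 20 simulations.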

Results

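Dermal fibroblasts were profiled from female mice that had eaten a high fat diet (HFD) or a normal diet (ND) for 6 months from an age of 2 months, and that were all killed on the same day. The cells came from dermis freed of the tissue beneath it and digested with collagenase. They were sorted for the fibroblast proteins Pdgfra and CD34 and against markers of blood, endothelial and epithelial cells, with 10000 cells per sample. Their RNA was amplified over 20 cycles and hybridised to mouse arrays. There were 4 ND and 4 HFD arrays. The submitters' labels exclude ND 4 by quality control without a reason, so ND 1, 2 and 3 were compared with HFD 1 to 4. The design text gives 4 animals per diet, and each specimen was taken as a separate mouse. The number of arrays limits the precision of every value. The question was how the diet alters the fibroblast transcriptome.

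In fibroblasts from HFD mice, 448 genes were higher and 466 lower than in ND fibroblasts, of 17097 genes tested (limma, adjusted p under 0.05), while 16183 did not pass. Most changes were modest, with a median of 1.41-fold and a largest of 2.66-fold, and 16 of the 914 genes reached 2-fold. The genes that rose included the secreted matrix protein Coch, the pentose phosphate enzyme Pgd, the Wnt modulator Dkk2, the mitochondrial kinase Pink1 and subunits of the respiratory chain. The genes that fell included Socs2, an inhibitor of growth hormone signalling, the adhesion molecule Ncam2, Ddah1, which degrades methylated arginines, and the desaturases Fads1, Fads2 and Scd1. At an unadjusted p under 0.01 there were 1832 genes, 933 higher and 899 lower, where 171 are expected by chance. That expectation gives no spread for correlated genes, and the grouping of HFD 2, 3 and 4 against the rest gave 1269.

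The 3′ minus 5′ difference of the control probe sets for Gapdh and Actb, a sign of RNA quality, also separated the diets, with a mean of −0.27 ± 0.08 log2 (SD, n = 3) in ND and −0.41 ± 0.03 (SD, n = 4) in HFD (exact two-sided permutation p = 0.0286, the smallest that 35 splits give for this measure). These transcripts were chosen after the values were seen. Their difference was −0.29, −0.335 and −0.18 in ND 1, 2 and 3, so ND 3 lay farthest from HFD. Of the other control transcripts, Tfrc also separated the diets (−0.59 to −0.57 in ND, −0.99 to −0.73 in HFD), while Pcx overlapped (−0.99 to −0.65 in ND, −1.0 to −0.72 in HFD). With the Gapdh and Actb difference as a covariate in limma, no gene passed the threshold (0 genes, with 604 at an unadjusted p under 0.05 and 98 under 0.01), and with the keratinocyte marker mean as a covariate 15 genes did. The median change of the 914 genes was 0.50 (median SE 0.10) without a covariate, 0.46 (SE 0.13) with the keratinocyte mean and 0.31 (SE 0.18) with the 3′ minus 5′ difference. The count was 6 with ND 4 included. It was 814, 485 and 11 without ND 1, ND 2 and ND 3 respectively. Without HFD 1, HFD 2, HFD 3 and HFD 4 it was 1072, 212, 6 and 9 respectively.

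**Figure D1:**
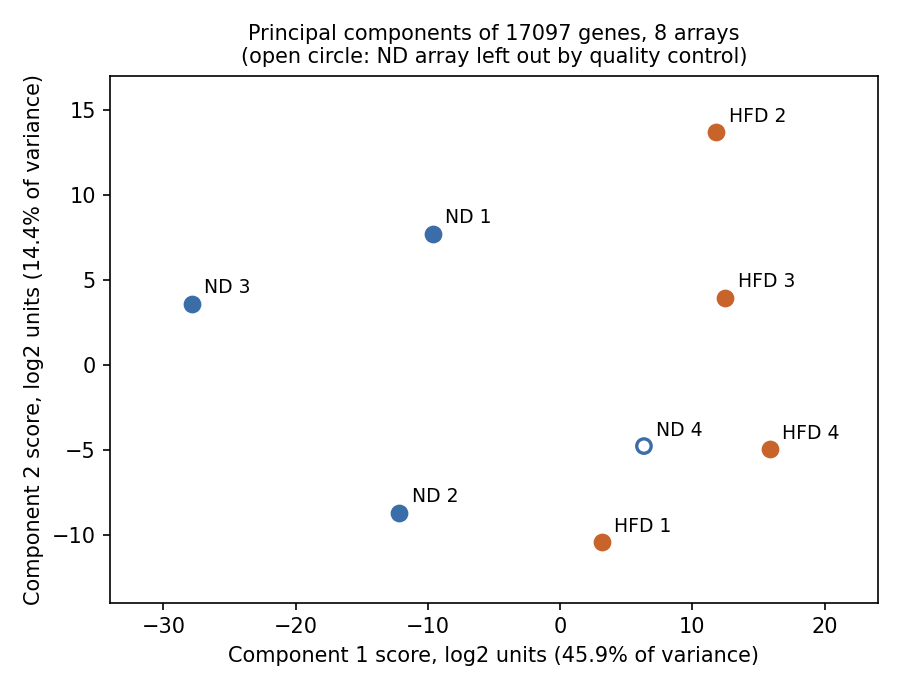
Scores of the 8 arrays on the first and second principal components of 17097 genes, in log2 units, with ND in blue, HFD in orange and the left-out ND array as an open circle. The first component held 45.9% of the variance. ND 3 lies at −27.85 on it, apart from ND 2 at −12.15 and ND 1 at −9.64. The HFD arrays lie between 3.15 and 15.84, and ND 4 at 6.34.

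Arrays of different diets lay farther apart than arrays of the same diet, with mean distances of 35.79 and 27.01 log2 units over all genes, a difference of 8.77 (exact one-sided permutation p = 0.0286, the smallest that 35 splits allow). With ND 4 included the difference was 4.89 (exact one-sided p = 0.0571), and without ND 3 it was 5.66, in a design whose smallest p is above 0.05. The spread between mice was similar in both diets, with a median SD per gene of 0.098 in ND and 0.097 in HFD. The median log2 ratio of the SDs, HFD over ND, was −0.004 (exact two-sided p = 0.857). HFD and ND arrays did not overlap in 3068 genes, or 17.9%, where independent genes would give 5.71% by chance, but the grouping of HFD 2, 3 and 4 against the rest gave 2930.

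Among genes past the threshold Coch showed the largest rise, from 8.53 ± 0.40 (SD, n = 3) in ND to 9.85 ± 0.58 (SD, n = 4) in HFD, a log2 change of 1.32 with a standard error of 0.29 (adjusted p = 0.0344). The neighbouring membrane protein genes Tmem176a and Tmem176b rose by 1.10 (SE 0.12, adjusted p = 0.0106) and 1.03 (SE 0.17, adjusted p = 0.0224). Pgd rose by 1.08 (SE 0.12) and Dkk2 by 1.08 (SE 0.26). Pink1 rose by 0.96 (SE 0.16), Rassf3 by 0.97 and Hif1an, which encodes a hydroxylase that restrains hypoxia-inducible factor, by 0.98, while its other probe sets, both dimmer, differed by 0.06 and −0.03. The chemokine-scavenging receptor Ackr4 rose by 0.94, the pentraxin Ptx3 by 0.92 and the autophagy gene Atg101 by 0.91. Zmat2, a zinc finger protein of the spliceosome, rose by 1.08, but its other probe set, which was dimmer, differed by −0.09 (unadjusted p = 0.194).

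Among genes past the threshold Socs2 showed the largest fall, from 9.86 ± 0.32 (SD, n = 3) in ND to 8.45 ± 0.27 (SD, n = 4) in HFD, a log2 change of −1.41 with a standard error of 0.17 (adjusted p = 0.0151), and its 3 other probe sets had the same sign. Ncam2 changed by −1.26 (SE 0.20), the zinc finger gene Zfp354c by −1.24 (SE 0.29) and Ddah1 by −1.09 (SE 0.17). The matrix gene Ecm2 changed by −1.08, Rbm12b2 by −1.07, the opsin gene Opn1sw by −1.05, and the ubiquitin ligase gene Dtx3l and the silencing factor gene Tasor2 by −1.03 each. In their mean over the arrays compared, Rbm12b2 (6.64) and Tasor2 (6.37) were below the median gene of 6.77. The other probe set of Rbm12b2, also dimmer, differed by −0.10 (unadjusted p = 0.122). Vamp7, a gene of vesicle fusion, changed by −1.03, the mitochondrial protease gene Yme1l1 by −0.99 (SE 0.16) and the noncoding RNA Kantr by −0.99. Of the 914 genes, 530 had other probe sets. In 276 of these all probe sets had the same sign, and in 66 another probe set went the opposite way at an unadjusted p under 0.05. Among the genes named in this text, a dimmer probe set also differed little for Rassf3 (0.04), Ptx3 (0.01), Ddah1 (−0.04), Kantr (−0.04), Yme1l1 (−0.09), Sdha (0.09), Hsd17b7 (0.02), Pik3ca (−0.03) and Itgb1 (0.02).

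**Figure D2:**
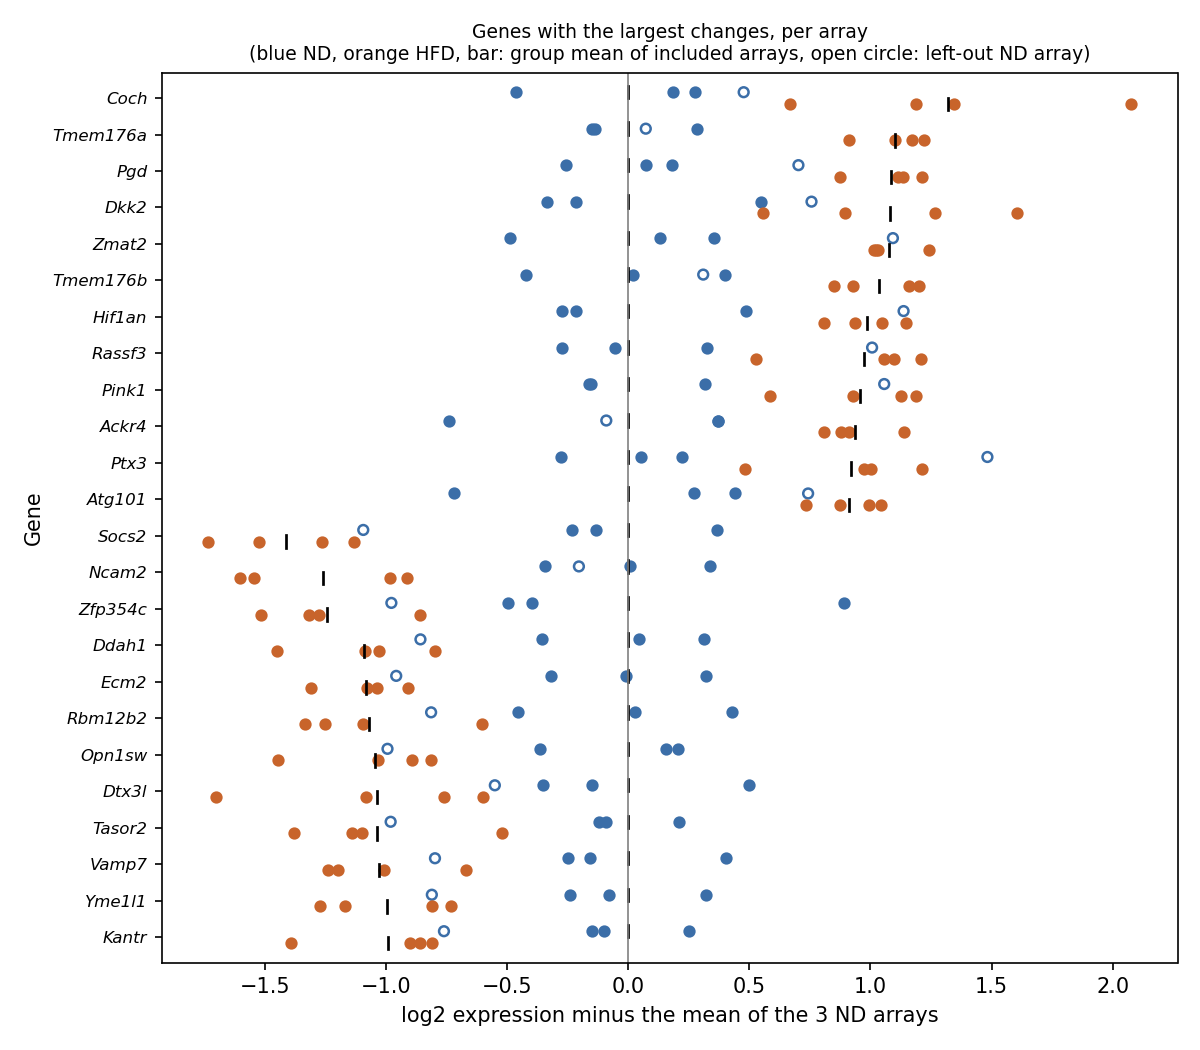
Log2 expression of the 12 genes with the largest rise and the 12 with the largest fall in HFD, among named genes past the threshold without overlap between the diets, per array, relative to the mean of the 3 ND arrays (blue ND, orange HFD, bars for the group means, open circles for the ND array left out by quality control). Coch has the largest rise of these, 1.32, and Socs2 the largest fall, −1.41.

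Subunits of oxidative phosphorylation, which makes ATP in mitochondria, were higher in HFD as a group, with 10 of 47 measured members higher, 0 lower and 37 not past the threshold. Adjusted over the list alone, 20 were higher and 0 lower. Uqcrb of complex III rose by 0.75 (SE 0.15, adjusted p = 0.0302), Ndufv1 of complex I by 0.59 (SE 0.10), the succinate dehydrogenase subunit Sdha by 0.56 (SE 0.09) and Uqcrfs1 by 0.44 (SE 0.09). Ndufs4, also counted as higher (0.48), has a dimmer probe set that went the opposite way (−0.46, unadjusted p = 0.0141). The list's median change was 0.22, with 40 of 47 members positive, and the list stood above other genes in camera (adjusted p = 3.02e-07). With an estimated correlation that call was lost (adjusted p = 0.956 with an estimated correlation, the smallest of any list, from an unadjusted p = 0.125). Fry gave an adjusted p = 0.252 (unadjusted p = 0.00971). The estimated correlation of the list was 0.29, above the preset 0.01. The diet grouping gave 2 lists past camera, but other splits, counted after the data were seen, gave between 0 and 7. The number of lists past camera therefore does not set the diets apart from other groupings. The 3′ minus 5′ difference given above moved with this list, and with it as a covariate the median was 0.12 (camera adjusted p = 0.00774, and 1.96e-09 to 0.956 over all settings). Among 24 glycolysis and hypoxia genes, the hexokinase Hk1 (0.43) and the phosphofructokinase Pfkp (0.42) rose, the glucose transporter Slc2a1 fell by 0.90 on the log2 scale (SE 0.20, adjusted p = 0.0387), and 21 did not pass. The other probe set of Hk1, which was dimmer, went the opposite way (−0.25, unadjusted p = 0.0501). Adjusted over the list alone, 4 were higher and 1 lower, and the list did not pass camera (adjusted p = 0.379), although it did without ND 2 (adjusted p = 0.0396) and with the keratinocyte covariate (adjusted p = 3.53e-05), over a range of up to 0.956 in the other settings.

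Genes of fatty acid synthesis moved in both directions. Of 17 measured, 4 fell, the desaturases Fads2 (−0.70, SE 0.16), Scd1 (−0.59, SE 0.14) and Fads1 (−0.56, SE 0.12) and the citrate carrier Slc25a1 (−0.57, SE 0.13), Mid1ip1 rose by 0.36 (SE 0.08) and 12 did not pass. Adjusted over the list alone, 5 were lower and 2 higher, and camera gave an adjusted p = 0.379. In the cholesterol synthesis list of 19 genes, the sterol-responsive regulator Insig1 fell by 0.69 on the log2 scale (SE 0.11, adjusted p = 0.0224), Hsd17b7 rose by 0.49, and 17 did not pass, with 1 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.626).

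Among 33 adipogenic regulators and adipocyte genes, the lipoprotein Apoe rose by 0.65 (SE 0.13), Scd1 fell as above, and 31 did not pass, with the same counts of 1 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.921). Cebpa differed by 0.62 with an adjusted p = 0.0654. Pparg, looked up after the values were seen, differed by −0.002 (SE 0.09). Of 32 genes of lipid uptake, storage and lipolysis, Apoe rose and the lipoprotein receptor Scarb1 fell by 0.28 on the log2 scale, with 2 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.878). Scarb1 was dim, at 5.65 in ND and 5.36 in HFD. Of 30 genes of fatty acid oxidation and PPAR targets, Acaa1a, a peroxisomal thiolase, rose by 0.56 (SE 0.14) and 29 did not pass, with 3 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.845).

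Matrix genes moved in both directions, and no matrix list passed camera. Of 46 structural matrix genes, 4 rose, tenascin N (Tnn, 0.80, SE 0.11, adjusted p = 0.0207), the laminin chains Lama2 (0.56, SE 0.10) and Lamc1 (0.35, SE 0.08), and Col16a1 (0.43, SE 0.11), while lumican (Lum, −0.34, SE 0.07) and Fbln1 (−0.26, SE 0.06) fell and 40 did not pass. Of the 2 other probe sets of Fbln1, the dimmer differed by −0.24 and the brighter by 0.01 (unadjusted p = 0.916), and the other probe set of Lamc1, also bright at 10.39, differed by 0.05 (unadjusted p = 0.566). There were 4 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.845). The collagen gene Col1a1, chosen after its values were seen, differed by 0.02 (SE 0.05). Among 25 genes of collagen processing, the crosslinking enzyme Lox rose by 0.45 (SE 0.09) and P4hb by 0.27, and Mia3, needed to export collagen, fell by 0.37 on the log2 scale (SE 0.07), with 4 higher and 5 lower adjusted over the list alone (camera adjusted p = 0.878). The 3 other probe sets of Mia3 differed by −0.76, 0.02 and 0.17. The membrane protease Mmp14 fell by 0.29 (SE 0.07), alone among 25 proteases and inhibitors, of which 2 were higher and 4 lower adjusted over the list alone (camera adjusted p = 0.878).

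Among 37 cytokine, chemokine and acute phase genes, the neutrophil chemokine Cxcl1 rose by 0.78 (SE 0.12, adjusted p = 0.0224) and Ptx3 by 0.92 (SE 0.17, adjusted p = 0.0253), and 35 did not pass. Il6 differed by −0.39 (SE 0.10, adjusted p = 0.0551). The count was 2 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.921). In the interferon response list, the RNA sensor Ddx58 fell by 0.46 on the log2 scale (SE 0.11, adjusted p = 0.0385), the other 27 members did not pass, and the count was the same adjusted over the list alone. The interferon list had a median of −0.08 (camera adjusted p = 0.169), and it passed camera without ND 1 (adjusted p = 0.0426), HFD 1 (0.0348) or HFD 3 (0.0384), with adjusted p up to 0.956 in the other settings. Oasl2 and Ifit1 of that list differed by −0.73 (adjusted p = 0.07) and −0.52 (adjusted p = 0.0723). None of 16 complement genes passed, 0 also when adjusted over the list alone (camera adjusted p = 0.903), and Cfb differed by 0.22 (adjusted p = 0.0777).

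Of 39 Wnt and BMP genes, Dkk2 (1.08) and Id1 (0.63, SE 0.12) rose, and Rspo1 (−0.52, SE 0.09), an enhancer of Wnt signals, Bmp4 (−0.35, SE 0.09), Bmp2 (−0.52) and Fzd2 (−0.33) fell. Adjusted over the list alone, 4 were higher and 6 lower (camera adjusted p = 0.92). Of 28 genes of the TGF-beta response and contractility, Ccn2 (0.50, SE 0.09), Itga5 (0.65, SE 0.16) and Itgb1 (0.32, SE 0.08) rose and none fell, and all 4 other probe sets of Itgb1 had the same sign. The count became 5 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.379). Ccn2 was below the median gene of 6.77, at 5.53 in ND and 6.03 in HFD. Among 25 genes of insulin, IGF and leptin signalling, the kinase subunit Pik3ca fell by 0.41 on the log2 scale and 24 did not pass, with 1 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.878).

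In the stress lists, the redox protein Txn1 (0.50, SE 0.08) and Aldh1a1 (0.89, SE 0.21) rose and Fmo1 (−0.47, SE 0.12) fell among 27 genes of oxidative stress and detoxification (camera adjusted p = 0.878), with the same 2 and 1 adjusted over the list alone. Among 28 genes of endoplasmic reticulum stress, the chaperone Dnajb11 rose by 0.74 (SE 0.15) and the transcription factor Atf4 fell by 0.30 on the log2 scale (SE 0.07), again 1 and 1 adjusted over the list alone. A dimmer probe set of Atf4 differed by 0.05. That list did not pass camera (adjusted p = 0.379), but did without ND 3 (median −0.11, adjusted p = 0.0389) and with the 3′ minus 5′ covariate (median −0.16, adjusted p = 6.48e-05), with up to 0.961 in other settings. Gadd45g (0.38) and Egr2 (0.45) rose among 34 immediate early and dissociation genes, with 3 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.878). Among 18 genes of growth arrest and senescence, the cell cycle inhibitor Cdkn2c rose by 0.46 (SE 0.10) and the lysosomal enzyme Glb1 fell by 0.34 on the log2 scale, as adjusted over the list alone (camera adjusted p = 0.878). No gene passed among 33 cell cycle genes (camera adjusted p = 0.878) or 61 ribosomal protein genes (camera adjusted p = 0.316), and adjusted over the list alone both counts were 0. Without ND 1 the ribosomal list had a median of 0.17 and passed camera (adjusted p = 1.2e-06, against up to 0.996 in other settings). This list had the highest estimated correlation of all (0.636), and with it the camera adjusted p over the 7 arrays was 0.956 (unadjusted p = 0.702).

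Cd34, a gene of the sort, was at 12.08 ± 0.02 (SD, n = 3) in ND and 12.10 ± 0.05 (SD, n = 4) in HFD. The probe set for Pdgfra was dim, at 5.92 in ND and 6.27 in HFD (adjusted p = 0.103). Of the genes of the excluded lineages, Ptprc (ND and HFD means of 4.08 and 4.03), Kit (4.25 and 4.25), Cd24a (5.65 and 5.79) and Epcam (5.23 and 5.27) were below the median gene of 6.77, Pecam1 was slightly above it (6.81 and 7.0), and none passed the threshold. Among 20 genes of the sort and of fibroblast identity, S100a4 rose by 0.49 (SE 0.07, adjusted p = 0.0224) and Lum fell, the same 1 and 1 adjusted over the list alone (camera adjusted p = 0.845). Of 18 papillary dermis genes Rspo1 fell (camera adjusted p = 0.92), 1 also adjusted over the list alone, and of 18 reticular and adventitial genes 0 passed by either count (camera adjusted p = 0.878).

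Keratinocyte markers were higher in HFD as a group, with a median change of 0.34 and all 19 measured members positive, though 0 members passed, also when adjusted over the list alone. Camera gave an adjusted p = 0.00558, and that call was lost with an estimated correlation (adjusted p = 0.956 with an estimated correlation, from an unadjusted p = 0.23). Other groupings of the arrays also gave lists past camera, as stated above. The mean of the list was 6.49 ± 0.17 (SD, n = 3) in ND and 6.99 ± 0.43 (SD, n = 4) in HFD (exact two-sided permutation p = 0.114). It was 6.43 in HFD 1 and between 7.02 and 7.49 in the other HFD arrays. The sort selected against EpCam, which marks epithelial cells, yet the keratins Krt10 and Krt5, looked up after their values were seen, were at 9.24 ± 0.57 and 8.19 ± 0.61 (SD, n = 3) in ND and at 9.83 ± 0.81 and 9.05 ± 1.08 (SD, n = 4) in HFD. Perp differed by 1.55 (SE 0.57, adjusted p = 0.143) and Krt1 by 1.14 (SE 0.47, adjusted p = 0.189). The call was also lost without the dim genes, although the median of the members left was larger (0.47, adjusted p = 0.482), and with the 3′ minus 5′ covariate, where the median was 0.17 (adjusted p = 0.328), over a range of 9.91e-07 to 0.956 in all settings.

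**Figure D3:**
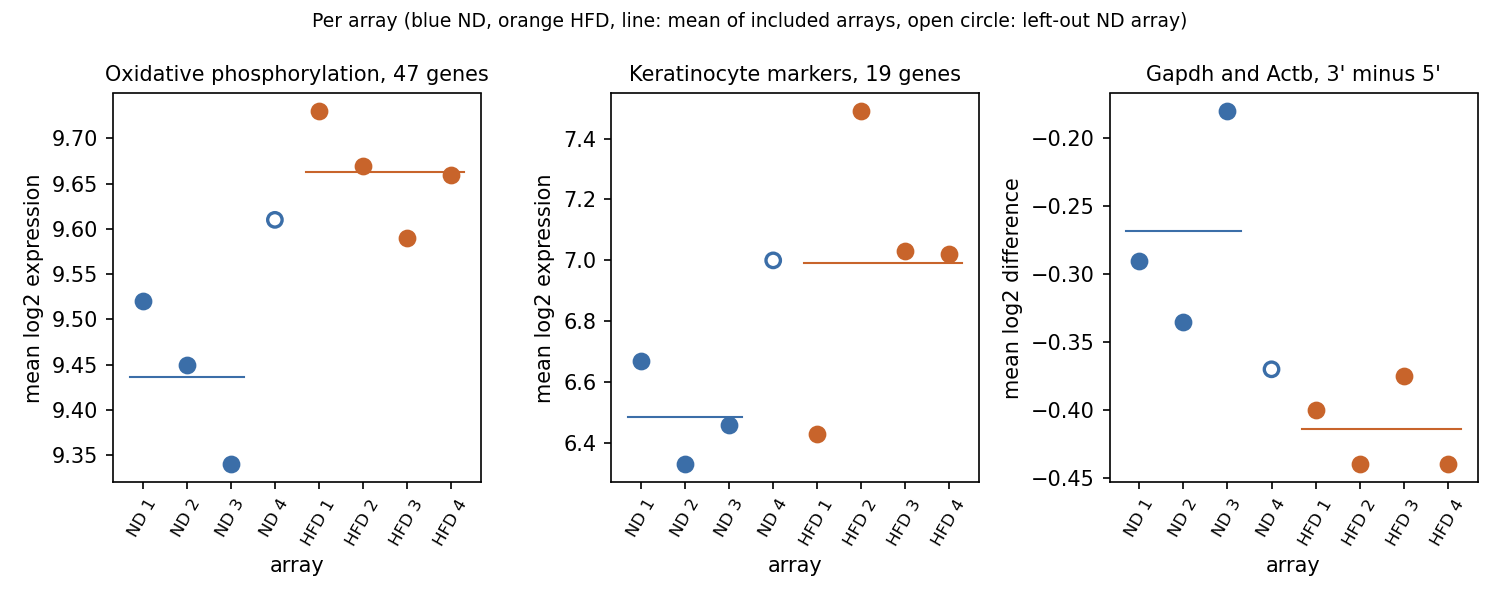
Mean log2 expression of 47 oxidative phosphorylation genes and of 19 keratinocyte markers, and the mean log2 difference between 3′ and 5′ control probe sets of Gapdh and Actb, for each array (blue ND, orange HFD, lines for the means of the included arrays, open circle for ND 4). The lowest HFD array in the oxidative phosphorylation mean is at 9.59 and the highest included ND array at 9.52, while ND 4 lies within the HFD range at 9.61. ND 3 is the lowest array in that mean, at 9.34. The 3′ minus 5′ difference is −0.335 or higher in ND 1, 2 and 3, and −0.375 or lower in the HFD arrays.

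The other cell types showed few calls. Tyrobp rose by 0.32 (SE 0.07) among 34 leukocyte genes (camera adjusted p = 0.878), and Heyl by 0.60 (SE 0.13) among 12 pericyte and smooth muscle genes (camera adjusted p = 0.316), each 1 also adjusted over the list alone. Both genes were below the median gene, Tyrobp at 5.60 in ND and 5.92 in HFD and Heyl at 5.45 and 6.05. The 2 other probe sets of Heyl, both dimmer, differed by −0.03 and 0.06. Pmp22 fell by 0.36 on the log2 scale (SE 0.06) among 14 Schwann cell and melanocyte genes, of which 2 were lower adjusted over the list alone (camera adjusted p = 0.722). Bmp4 fell among 19 genes of the dermal papilla and sheath, with 1 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.845). No member passed, by either adjustment, among 10 mast cell (camera adjusted p = 0.845), 22 endothelial (0.878), 15 mature adipocyte (0.878), 16 skeletal muscle (0.729) and 5 erythrocyte genes (0.626). The leukocyte list passed camera with the 3′ minus 5′ covariate (median 0.08, adjusted p = 0.0399, against up to 0.996 in other settings). In 13 of the 35 lists, none of them past camera, the signs of median, mean and test differed. By fry's test for change in either direction, 24 lists passed (smallest adjusted p = 0.000156, for structural matrix and for papillary dermis genes). This test does not compare a list with other genes, and 22.1% of all genes were at an unadjusted p under 0.05 in limma. Complement (fry adjusted p = 0.0023) and cell cycle (0.0317) passed it with 0 members past the threshold, so it does not single out these lists.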

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

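The tests with the keratinocyte mean and the 3′ minus 5′ difference, and the spread of positions between arrays, were chosen after the data had been seen.

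The ND array excluded by quality control entered only the alternative fits with all 8 arrays, and its expression lay nearer to HFD than to ND. On an axis from 0 at the ND mean to 1 at the HFD mean, over 1832 genes, it lay at 0.764 (bootstrap SE over genes 0.01), where the other ND arrays, each on an axis made without it, lay between −0.349 and 0.421 and the HFD arrays between 0.604 and 1.11, and it was nearer the HFD mean in 752 of the 914 genes that passed. A swap would need an HFD array out of place, and HFD 1, the lowest, lay at 0.604, above the bound of 0.5 set beforehand but by less than the pooled SD of positions within diets (0.316), so a swap stays open. Removing the effect of the keratinocyte mean, which was 7.0 in this array, put the position at 0.805 (SE 0.01), and removing that of the 3′ minus 5′ difference, −0.37 in this array, at 0.633 (SE 0.014), both less than that SD above 0.5, so keratinocyte RNA and RNA quality stay open, since the bootstrap bound set beforehand left out the spread between arrays. A wrong label with no partner in the series, the unstated quality problem and variation between mice stay open and were not tested.

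Of 199 genes and lists examined, 13 had an HFD array far from the other HFD arrays, where chance gives about 1 in 20. That is near the share found, and the items are not independent, so the values below are listed without a claim of an effect. HFD 4 was at 6.76 for Kantr, 12 for P4hb, 7.41 for Fads2, 6.87 for Usp18 and 6.65 for Pvalb, with the nearest other HFD array at 7.25, 11.84, 7.79, 7.54 and 6.73. HFD 1 was at 9.49 for Aldh1a1, 10.29 for Hmgb1, 5.94 for Cd53 and 11.31 for Hba-a2, with the nearest at 10.28, 10.08, 5.46 and 11.26. HFD 2 was at 9.80 for Zmat2, 12.22 for Klf4 and 6.67 for the mean of the Schwann cell and melanocyte list, with the nearest at 9.59, 12.32 and 6.62. HFD 3 was at 9.24 for Plat, with the nearest at 9.47.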

How the results depend on the processing

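The GC background, keratinocyte and 3′ minus 5′ settings were added after seeing the data. Of the 914 genes, 877 stayed at an unadjusted p under 0.05 with all 8 arrays, 908 with the keratinocyte covariate and 237 with the 3′ minus 5′ covariate. Choosing these genes at a stricter threshold on the same arrays favours their staying. All 914 stayed without HFD 3, although 6 genes passed the adjusted threshold there. The count of genes past adjusted p 0.05 was 6 with all 8 arrays, between 6 and 1072 when each array was left out, 1387 with the dimmer genes left out (fewer genes tested), 400 with the mean of probe sets, 1459 with a residual component, 15 with the keratinocyte covariate, 0 with the 3′ minus 5′ covariate, 1947 at adjusted p 0.1 and 16 at 2-fold. At an unadjusted p under 0.01 the count was 898 with all 8 arrays, 970 to 1980 when each array was left out, 841 with the keratinocyte covariate and 98 with the 3′ minus 5′ covariate. The GC background block gave 653 and 1806 genes. With ND 4 included or ND 3 left out, the median change of the 914 genes went from 0.50 to 0.40 and 0.43. Specimen numbers showed no sign of pairing the mice (correlations of deviations −0.182, −0.291 and −0.053, and 0 of 3 arrays fit their own number best), but 3 pairs are too few to exclude it. A replicate block left 1 gene past and 825 at an unadjusted p under 0.01. Lists past camera numbered 2 to 4 when each array was left out, 1 without the dimmer genes, and 0 both with an estimated correlation and in fry. Oxidative phosphorylation (0.22) and keratinocyte markers (0.34) lost their call with an estimated correlation (camera adjusted p = 0.956 each, the smallest of any list) and in fry (0.252 and 0.403). Their unadjusted p with an estimated correlation was 0.125 and 0.23. Keratinocyte markers also lost it without dimmer genes (0.47) and with the 3′ minus 5′ covariate (0.17), and stood at −0.044 with their own mean as covariate, which that covariate fixes. With the keratinocyte covariate glycolysis passed (0.30), and with the 3′ minus 5′ covariate endoplasmic reticulum stress (−0.16) and leukocyte genes (0.076) did. Leaving out each array gave medians of −0.105 to −0.055 for interferon response, 0.062 to 0.277 for glycolysis, −0.114 to 0.017 for endoplasmic reticulum stress and 0.027 to 0.175 for ribosomal proteins, each past the threshold in some. The separation of the diets was 4.89 with all 8 arrays and 5.66 to 11.2 when each array was left out. Counts of genes or lists stayed within 1.5 times the reported count in 45 of 69 values. Of 805 list medians, 684 kept direction and side of the threshold, and 105 without a call in either fit changed sign or came to 0. The spread within diets passed in 0 of 13 settings and changed sign in 4. For named genes 2572 of 3408 values kept direction and side, 36 without a call changed sign or came to 0, 717 lost a call, 83 gained it and 0 reversed with a call, which the choice of genes by size or p favours. Apart from the constructions named, the cause was not tested. Dim genes, near background signal, hold few calls, since 88.4% of the 914 lay above the median gene.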

Other observations

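The counts over other splits of the arrays, the families of gene symbols and the fits with the keratinocyte mean or the 3′ minus 5′ difference were chosen after the data had been seen, the last with bounds set before their results but with their spread over arrays and splits added after them.

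Genes with symbols starting with Psm, which include the proteasome subunits, were the only family past camera among 62 families of gene symbols. Their median change was 0.16 over 47 members (camera adjusted p = 0.00245). With an estimated correlation the adjusted p was 0.849 (unadjusted p = 0.286). Psma6 rose by 0.60 (SE 0.13, adjusted p = 0.0318), Psmd7 by 0.54 (SE 0.11) and Psma3 by 0.36 (SE 0.08), and 0 members passed the threshold as lower. The 2 other probe sets of Psmd7, both dimmer, differed by 0.01 and 0.06. The integrator subunits (Ints, 15 members) had a median of −0.17 with 2 lower and did not pass (camera adjusted p = 0.111). The families that hold respiratory chain subunits did not pass either. Cox (25 members) had a median of 0.129 with 0 higher and 0 lower (camera adjusted p = 0.111). Nduf (42 members) had a median of 0.135 with 4 higher and 1 lower (camera adjusted p = 0.186). The smallest p-values of all belonged to genes outside the lists. The amino acid transporter Slc43a1 fell by 0.81 on the log2 scale (SE 0.07, adjusted p = 0.00471), the secreted semaphorin Sema3b by 0.85 (SE 0.08), the actin-binding protein Clmn by 0.83 (SE 0.08) and the stromal protein Sned1 by 0.64 (SE 0.07). Other, dimmer probe sets differed by −0.24 to 0.04 for Clmn and by −0.19 and −0.12 for Sema3b, while the gene Atad5, which unloads the replication clamp, rose by 0.54 (SE 0.05) at a dim level of 4.71 in ND and 5.24 in HFD.

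Among the 35 splits of the arrays, 1, the real one, gave as many as 914 genes (5 in the highest other) and 1 gave as many as 1832 at an unadjusted p under 0.01 (1269 in the highest other, HFD 2, 3 and 4 against the rest). For these 7 arrays that is a share of 0.0286, the smallest that 35 splits allow, so it argues against chance only at that level. Both counts were chosen after the data had been seen, and with ND 4 included 6 genes passed, so chance is not excluded. Lists past camera numbered 2 in the real split and between 0 and 7 in the others, so that count does not set the real split apart. With the keratinocyte mean as covariate 841 genes stayed at an unadjusted p under 0.01, but 2 of 35 splits fitted with it, the real one included, gave as many (1266 in the highest other), which the bound set beforehand left out, and along axes made without the array placed the diets lay 0.58 apart with it (SE 0.33 over arrays), within 2 SE of 0, so keratinocyte RNA cannot be told apart from diet with so few arrays. The calls fell to 15 and the median change of the 914 genes from 0.50 (median SE 0.10) to 0.46 (SE 0.13), mainly through the wider error, since the uncorrected changes with that error gave 7 calls and the corrected changes with the former error 841. With the 3′ minus 5′ difference as covariate 98 genes stayed at that level, and the median change went to 0.31 with an SE of 0.18, where the wider error alone left 0 calls and the smaller change alone 137. RNA quality and diet cannot be told apart for these genes, because ND 1 to 3 and the HFD arrays do not overlap in that difference, and an effect of the diet on the fibroblasts stays open beside both.

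Oxidative phosphorylation genes had a median change of 0.22, reached by 1 of 35 splits, but the highest other split gave 0.21, a gap smaller than the errors of the medians below, so that count is weak evidence against chance. A trend with expression level is argued against, because the median lay above all 10000 random lists matched on mean expression (percentile 100, highest random list 0.20). Keratinocyte RNA as the whole cause is argued against too, because with that covariate the median was 0.22 (bootstrap SE over genes 0.05), above the bound of 0.11 set beforehand, and the list mean was 0.24 with an SE of 0.08 over arrays, more than 2 SE above 0, although a part in the change is not excluded. With the 3′ minus 5′ covariate it was 0.12 (SE 0.03), too near to 0.11 to decide, so RNA quality cannot be told apart from diet here. A rise of respiratory chain transcripts with the diet is a hypothesis that stays open.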
